A study of Oryza sativa with 6 samples.

How the data were processed

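Gene expression was measured in laser-captured nucellar projection cells of 6 rice seed samples, with 2 arrays in each of 3 groups. Per the file headers, the authors scanned 1-colour (Cy3) arrays of Agilent design 15241 with Feature Extraction 10.7.3.1, and the deposited spot signal is an intensity on a linear scale, background-subtracted and detrended within each array and not normalized between arrays. The deposited quality flags hold 0 or 1 per spot. The authors' deposited value table is on a log2 scale. Its 6 columns hold the same set of values, which means that it was quantile normalized, each column has a median of 10.4, and it correlated with the log2 spot signal of the same array at 0.998 or above. It was not centred per gene, and its direction and scale are those of the spot signal. The method used for it is not given in the sources used here.

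Each array had 45151 spots, of which 1417 were controls and were left out. Spots marked as non-uniform or population outliers were removed, 0.0983% to 0.183% of spots per array. The log2 of the processed signal minus the array's 75th percentile was averaged over the spots of a probe. A further 48 probes, which the array design names as its own rice controls, were left out of the tests. A probe was kept where it was well above background, in at least 0.5 of its spots, on both arrays of at least 1 group, which left 32420 of 42429 probes. Where several kept probes named a locus, as at 6474 loci, the brightest over all arrays stood for it. This gave 22283 genes and microRNA probes, with 22184 loci.

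All 6 arrays entered 1 fit in limma 3.58.1 under R 4.3.3, with a mean per group, empirical Bayes moderation and Benjamini-Hochberg adjustment at 0.05. The fit had 3 residual and 2.36 prior degrees of freedom. The contrasts were the mean of the lines minus wild type, each line minus wild type, and line 14 minus line 2. Group tests used limma's camera with a preset correlation of 0.01, camera with an estimated correlation, and fry. Figures were drawn with matplotlib 3.10.9.

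The samples, the main design, the alternatives and the rule for named genes were fixed before the data were examined. That rule took OsMADS29, whose locus ID was set from general knowledge, and the called genes with the largest fitted rises and falls whose arrays do not overlap, leaving out genes with no annotated function. Probe names carry locus IDs, sequence accessions or microRNA names and no function. The reference gene table, with 39387 genes, matched 0 of the locus IDs. The rule was therefore narrowed to the 2 largest fitted rises and the 2 largest fitted falls, by ID, an order that is not one of true size where a group was dim. For the same reason 0 of the 30 gene lists fixed in advance could be formed. In their place, after the data were examined, 26 groups of at least 5 probes were taken from the probe names, covering chromosomes, evidence classes, probe regions and microRNA families.

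The alternatives covered normexp background correction with an offset of 50 and quantile normalization, quantile or median scaling, the authors' value table, the filter on dim probes, every probe on its own, an intensity trend, replicate number or slide as a block, the arrays in the fit, the threshold, and each array left out in turn. The files hold no mean spot signal, so normexp used the median spot signal, which differs from what was planned. Array weights, the other OsMADS29 probe and a split of the wild-type arrays between the lines were added after the data were examined.

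The code was tested on simulated data for the comparison of both lines with wild type, over 22243 genes with 200 changed genes in each of 5 runs. It recovered 0% of changes of 1 on the log2 scale, 4.4% of changes of 2, 63.6% of changes of 4 and 87.2% of changes of 6, with 19 false calls among 407. The simulation gave all arrays the same spread for a gene, whatever its signal, and shifted both lines alike. Recovery and false calls in the measured data may therefore differ. The number of arrays limits the precision.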

Results

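Transcript levels were measured in cells of the nucellar projection of rice seeds, Oryza sativa, at 3 days after flowering. The nucellar projection is a maternal tissue of the young seed that lies next to the vascular bundle. The cells were cut out by laser capture microdissection, in which a laser isolates chosen cells from a fixed section, and their RNA was amplified in 2 rounds and hybridised to 1-colour Agilent arrays. The 6 arrays formed 3 groups of 2, namely wild type of the cultivar ZH11, A-OsMADS29 line 2 and A-OsMADS29 line 14. The labels call both lines OsMADS29 mutants and do not spell out the prefix. OsMADS29 is a MADS-box transcription factor, and the series title ties it to the breakdown of nucellus tissue. The labels name independent biological samples and do not say how many plants or seeds gave each. Between 72.8% and 79.8% of the 42429 probes were well above background on each array, no spot was saturated, and the number of arrays limits the precision.

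The wild-type arrays resembled each other least. Pearson's r across genes, which are not independent replicates, was 0.916 between the wild-type arrays, 0.945 between the line 2 arrays and 0.958 between the line 14 arrays. Of the genes tested, 26.1% lay more than 2-fold apart between the wild-type arrays, against 15.9% in line 2 and 16.2% in line 14. Wild-type replicate 1 had the lowest mean r with the other arrays, at 0.907. Wild type and line 2 shared slide 1, and line 14 alone was on slide 2, so a difference of line 14 cannot be told apart from a difference between slides.

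OsMADS29 (locus Os02g0170300) was well above background on all 6 arrays and was not called different in the lines. Its log2 signal relative to the array's 75th percentile was 0.63 ± 0.35 (SD, n = 2) in wild type, 0.31 ± 0.83 (SD, n = 2) in line 2 and 0.09 ± 0.12 (SD, n = 2) in line 14. The mean of the lines differed from wild type by -0.43 (SE 0.41, 95% confidence interval -1.46 to 0.60, limma adjusted p = 0.876). The lower bound of that interval is a level 2.76-fold lower, so a larger fall of the transcript at this probe lay outside it. The difference was -0.32 in line 2 (limma adjusted p = 0.983) and -0.54 in line 14 (limma adjusted p = 0.895). An exact two-sided permutation test of the 4 line arrays against the 2 wild-type arrays gave p = 0.4, where the smallest p that the 15 splits allow is 0.0667. The probe covers the end of the coding sequence and the 3' UTR. The other OsMADS29 probe, in the 5' UTR and coding sequence, gave -0.16 (95% confidence interval -1.29 to 0.97, limma adjusted p = 0.968). The labels do not give the part of the gene that the lines alter, so neither probe settles whether the arrays match their labels.

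**Figure D1:**
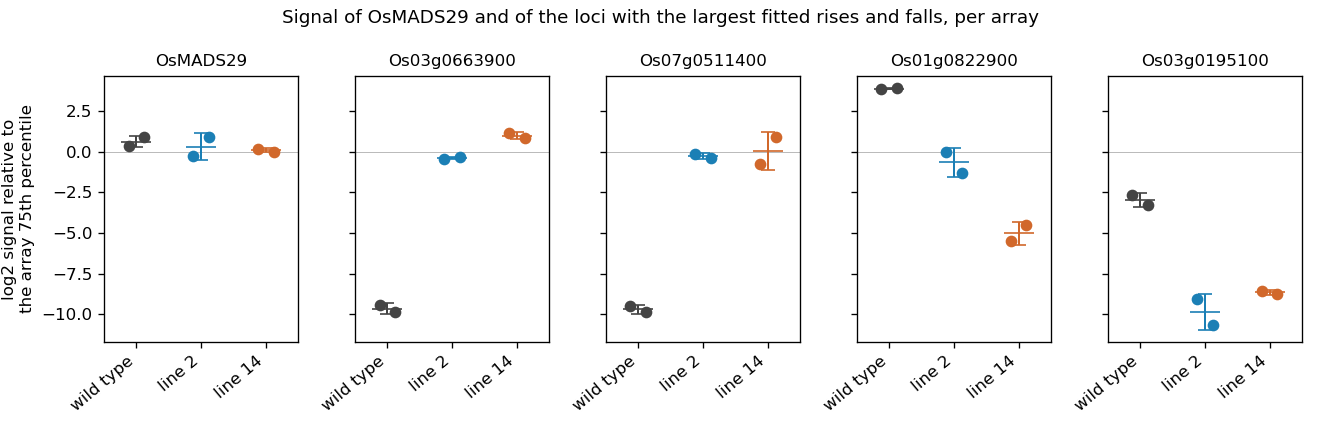
Log2 signal relative to the array's 75th percentile for OsMADS29 and the called loci with the 2 largest fitted rises and the 2 largest fitted falls, in wild type, line 2 and line 14. Points are arrays, dashes are group means and bars are the SD (n = 2); the line 2 arrays lie on both sides of wild type for OsMADS29, while Os03g0663900 and Os07g0511400 are near -9.66 and -9.69 in wild type, not well above background.

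The comparison of both lines with wild type asked which transcripts differ when OsMADS29 is altered. Among 22283 genes and microRNA probes, 32 were called in limma, 18 higher and 14 lower in the lines. Os03g0663900 rose to 414-fold above a floor set for wild type, where it was not well above background (fitted log2 difference 9.95, SE 0.27, limma adjusted p = 0.0028). Os07g0511400 rose to 313-fold above such a floor (fitted log2 difference 9.58, SE 0.51, limma adjusted p = 0.0228). Os01g0822900 fell from 3.88 ± 0.03 (SD, n = 2) in wild type to -0.66 ± 0.91 (SD, n = 2) in line 2 and -5.02 ± 0.69 (SD, n = 2) in line 14. Its log2 difference was -6.72 (SE 0.48, limma adjusted p = 0.0421), a level 106-fold lower, and its 7 probes gave values from -6.72 to -7.68. Os03g0195100 in wild type stood 39.6-fold above a floor set for the lines, where it was not well above background on any of the 4 arrays (fitted log2 difference -6.29, SE 0.50, limma adjusted p = 0.0445). The size of the differences from a dim group depended on the background correction. After normexp, whose offset of 50 raises dim signals, the log2 difference was 6.49 for Os03g0663900, 6.18 for Os07g0511400 and -3.03 for Os03g0195100. Each was smaller in size than the fold above the floor, so these folds hold for the processed signal alone. For the floor, the dim group stood at the higher of its own signal and the lowest signal among probes well above background on each array. Some probes not well above background lay over that lowest signal, so these folds are not strict lower bounds. The files pair no locus with a gene name or function, so these loci are given by ID and the others by number.

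Most of the 18 genes called higher went from undetected to detected. In wild type, 17 of them were not well above background on either array, and 15 of the 18 were well above background on all 4 line arrays. All 14 genes called lower were well above background on both wild-type arrays, and 6 of them on none of the 4 line arrays. By the evidence class that the probe names carry, 17 of the 32 came from cDNA, 11 from predictions supported by expressed sequence tags and 4 from predictions alone. Among the 22243 genes with complete values these classes held 16662, 4102 and 1381, so cDNA made up a smaller share of the called genes than of those tested. Of the 32, 0 were microRNA probes, although 12 microRNA probes had an unadjusted limma p under 0.05. In all 32 the line arrays and the wild-type arrays did not overlap. Of all genes tested 16.5% met that condition, where chance gives 13.3%.

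The set of called genes changed with every array left out. Each such fit leaves 1 group with 1 array and fewer degrees of freedom. A lost call therefore need not come from the values of the array left out. The fitted log2 difference of Os03g0663900 stayed between 9.72 and 10.18. Without wild-type replicate 1 the count of 32 became 1, without wild-type replicate 2 it became 106, of which 12 were among the 32, without line 14 replicate 1 it became 2, and it was 0 without line 2 replicate 1, line 2 replicate 2 or line 14 replicate 2. With no filter on dim probes, or only probes well above background on all 6 arrays, 4 genes were called. The latter filter leaves out any gene dim in wild type, as 17 of the 18 called higher were. With slide as a block line 14 is absorbed by its slide, so the 5 genes called then are those of line 2 against wild type. Of the genes tested, 1756, or 7.88%, had an unadjusted p under 0.05. The balance of the calls moved with the processing, to 15 higher and 25 lower after normexp with quantile normalization and to 16 higher and 19 lower in the authors' deposited values, and was 92 higher and 14 lower without wild-type replicate 2.

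**Figure D2:**
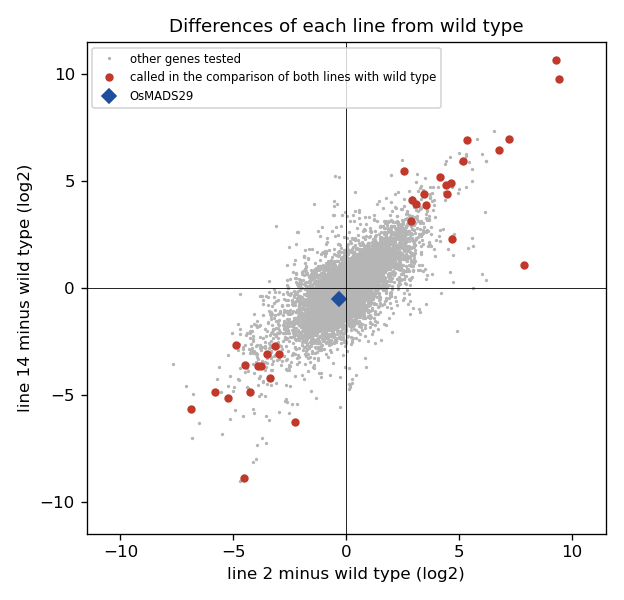
Log2 difference from wild type in line 2 (horizontal axis) and in line 14 (vertical axis) for each gene tested, grey. Red points are the 32 genes called in the comparison of both lines with wild type, which all have the same sign in both lines, and the blue diamond is OsMADS29, at -0.32 and -0.54.

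Taken singly, each line gave fewer calls. Line 2 differed from wild type in 5 genes, 4 higher and 1 lower, and line 14 in 9, 7 higher and 2 lower. Os03g0663900 was called in both, with fitted log2 differences of 9.27 in line 2 (limma adjusted p = 0.00882) and 10.64 in line 14 (limma adjusted p = 0.00424), and so was Os07g0511400, with 9.42 (limma adjusted p = 0.0449) and 9.75 (limma adjusted p = 0.0422). Os01g0822900 was called in line 14, at -8.91 (limma adjusted p = 0.0422), and was -4.54 in line 2 (limma adjusted p = 0.116). Os03g0195100 had fitted differences of -6.89 in line 2 (limma adjusted p = 0.0793) and -5.68 in line 14 (limma adjusted p = 0.0801). With any 1 array left out the calls of each line fell, in fits with fewer degrees of freedom and 1 group of 1 array.

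The direct comparison of line 14 with line 2 called 0 genes in limma, and 770 genes, or 3.46%, had an unadjusted p under 0.05. The smallest adjusted p was that of 1 of the 18 genes called higher in the pooled comparison (limma adjusted p = 0.0828). In line 2 it stood 51.2-fold above a floor set in the same way for line 14. That gene, picked out after its values were seen, was called in line 2, at 89.6-fold above the floor for wild type (limma adjusted p = 0.0194). It was not called in line 14 (limma adjusted p = 0.625), where it was not well above background on either array, as in wild type. Os01g0822900 was -4.37 in line 14 relative to line 2 (95% confidence interval -5.78 to -2.96, limma adjusted p = 0.553). The 95% confidence interval reached a median of 1.04 to either side of the difference on the log2 scale. Differences several times that size also went uncalled after adjustment.

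Called in both lines were 3 genes, all higher. Independent lists of these lengths would share 0.00126 higher genes and 8.98e-05 lower genes, and 50 simulations of unchanged lines against the same controls shared 0. Neither value tests the 3 genes. Independent lists ignore the wild-type arrays that the comparisons share. Where no gene changes, adjustment seldom leaves a call to share, so the simulated 0 was close to fixed in advance. Across 22243 genes the differences of the lines from wild type had r = 0.727, against 0.504 in the simulation. Their signs were the same in 73.4% of genes, against 66.7%. The simulation gave all arrays the same spread for a gene. The root-mean-square log2 difference between replicates was 1.21 in wild type, 0.99 in line 2 and 0.85 in line 14. A more variable shared control raises r and the same-sign share, so the simulated values are too low a yardstick for these. The covariance of the differences was 0.584, against 0.487 simulated. The difference of the wild-type arrays gave a variance of 0.368 for the wild-type mean, which leaves 0.217. With 1 wild-type array as the control of line 2 and the other as that of line 14, a check added after the data were examined, r was 0.204 or 0.181, the covariance 0.229 or 0.206 and the same-sign share 50.3% or 49.9%, depending on which array served which line. Each line then had 1 control array, so these values carry no test. The mean of the 2 covariances matches the 0.217 above almost by construction, so it is not a second result. Fits without 1 array leave 1 group with 1 array and fewer degrees of freedom, so the loss of these calls in such fits does not test them.

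MicroRNA probes as a group lay lower in the lines without passing the test. The 98 microRNA probes tested, 28 for mature and 70 for flanking sequence, had a median log2 difference of -0.31 (limma camera adjusted p = 0.0984). Most were thus not probes of a mature sequence. A shift of the group, or of a family in it, does not by itself show a change in mature microRNA. Probes of the miR166 family, a conserved plant microRNA family known to target class III HD-ZIP transcription factors, were the only group of the 26 tested to pass, with a median of -0.42 over 19 probes, 17 of them lower (limma camera adjusted p = 0.00853). With an estimated correlation the miR166 result was lost (adjusted p = 0.962), and limma's fry gave an adjusted p of 0.992. It was also lost without line 2 replicate 1 (camera adjusted p = 0.133), wild-type replicate 2 (0.425) or line 14 replicate 2 (0.0625). The number of microRNA probes well above background was 164 and 102 on the wild-type arrays, 86 and 144 in line 2 and 80 and 80 in line 14. None of the 12 chromosomes shifted as a group (limma camera adjusted p = 0.977 for each). Probes in the 5' UTR and coding sequence had a median difference of 0.16 over 177 probes (limma camera adjusted p = 0.328). At loci with probes at both ends, the median 5' minus 3' signal, centred over arrays, was 0.30 and 0.30 in line 2, -0.20 and -0.09 in line 14, and -0.34 and 0.08 in wild type.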

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

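The count of genes called in exchanged groupings, the limit to bright probes, the interval on neighbouring pairs, and the reading of the shared accessions as undecided were chosen only after the results they bear on were seen; the other tests here were set beforehand.

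Of the design's own rice control probes, those of the kind named genome were well above background in 9.17% to 13.3% of their 240 spots per array. The negative controls reached 0.654% to 3.27%. These probes entered no comparison.

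Wild-type replicate 1 was the array least like the others. Differences of scale between arrays cannot account for this, since its mean Spearman correlation with the other arrays, which no rescaling changes, was 0.941 and the next lowest was 0.956. Loss of 5' signal in amplified or degraded RNA may contribute, because its median 5' minus 3' signal was -0.34, below the range of -0.20 to 0.30 on the other arrays. The lowest array always lies outside the range of the others, so this is weak evidence. Line 14 replicate 1 was next lowest, at -0.20, yet its mean Spearman correlation was 0.958, above the 0.956 of line 2 replicate 2. The test does not show how much of the distance the loss of 5' signal accounts for. The kind of cells captured was not tested.

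OsMADS29 was not called lower in the lines, and 1 explanation could be a wild-type array exchanged with a line array. The test set beforehand counted probes well above background on all arrays of 1 side and none of the other, and it came out as an exchange would have it, with up to 400 such probes in the 8 groupings that exchange 1 array against 220 as labelled. Of the 8, only the groupings of line 2 replicate 2 with wild-type replicate 1, at 400, and with wild-type replicate 2, at 311, reached 220. Line 2 replicate 2 had the most probes well above background, at 79.8%. The count of genes called, turned to after the test set beforehand, went the other way, with 0 genes in each of the 8 groupings and 42 as labelled. So did the count limited to probes at least 16-fold over the detection floor, with at most 16 in the 8 groupings and 31 as labelled. The tests disagree, so an exchange and correct labels cannot be told apart from them, and a single wrong label also stays open. An effect of the construct that leaves the transcript in place was not tested.

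The 220 all-or-none probes, 91 absent in wild type and 129 absent in the lines, were no more than other groupings gave. As many appeared in 4 of the 15 groupings of the arrays, and 15 groupings are too few for a share under 0.05. The others were 400 for wild-type replicate 1 with line 2 replicate 2, 311 for wild-type replicate 2 with line 2 replicate 2, and 303 for the grouping that follows the slides. Line 2 replicate 2 had the most probes well above background, at 79.8%, and the line 14 arrays the fewest, at 72.8% and 72.9%. The groupings above 220 thus held the array with the most probes detected or the arrays with the fewest. Among probes at least 16-fold over the detection floor the labelled grouping gave 31 and the highest other 20. Sequence shared with another locus stays open, since a source accession shared with another locus, found for 0.455% of these probes, is rare among all probes kept, at 2.18%, and misses copies with accessions of their own; a share under 1 in 20 was to count against it, which almost any set of probes would meet. Linked chromosome segments that differ between the lines and wild type stay open, since the 3 neighbouring pairs of loci (95% exact Poisson interval 0.619 to 8.77) are too few to set against random draws of 0 to 5, although lying within that range was to count against them.

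For the 32 genes called, a fit with the 4 line arrays as 1 group called 42, and 1 of the 15 groupings, the labelled one, gave as many. The highest other was 1 gene, for the grouping that follows the slides, and 15 groupings are too few for a share under 0.05.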

How the results depend on the processing

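Array weights, the other OsMADS29 probe and the split of the controls, whose values stand with the genes called in both lines, were tried only after the data were examined. No named gene changed sign under any alternative run, but in some the majority of calls turned from higher to lower. For both lines it turned to 15 higher and 25 lower after normexp, which here included quantile normalization. It turned to 16 and 18 after quantile normalization alone and to 16 and 19 in the authors' table. For line 14 the calls went from 7 and 2 to 10 and 14 after normexp, and to 17 and 14 after quantile normalization alone. With probes above background on all 6 arrays they were 1 and 3 for both lines and 0 and 1 for line 14. That filter leaves out every gene dim in wild type, as 17 of the 18 called higher were, so its turn was largely built in. Both lines against wild type, 32 genes, gave 4 with no filter, 4 with probes above background on all 6 arrays, 5 with array weights and 69 at an adjusted p under 0.10. Slide as a block gave 5, which is the line 2 comparison, since line 14 has a slide to itself. The count stayed within 1.5 times in 8 other alternatives, but not always the genes, with 14 of the 32 among 40 called after normexp and 10 among 27 called with an intensity trend. Of the 8, a limit to changes of at least 2-fold could remove no call, since the smallest called log2 difference was 2.93 in size. Quantile normalization and the authors' table, itself quantile normalized, are not separate checks. Line 2, 5 genes, gave 10 after quantile normalization, 10 in the authors' table, 2 with no filter, 0 with the strict filter, 2 with every probe on its own, 9 with an intensity trend, 37 at 0.10, 2 with array weights, and 0 with only its slide or only the 2 groups compared. Line 14, 9 genes, gave 24 after normexp, 31 after quantile normalization, 31 in the authors' table, 1 with no filter, 1 with the strict filter, 14 with every probe on its own, 54 at 0.10, 1 with array weights and 0 with only the 2 groups compared. Line 14 against line 2, 0 genes (770 at an unadjusted limma p under 0.05), gave 1 after quantile normalization, in the authors' table, at 0.10 and with array weights. The 3 genes called in both lines became 6 after normexp, 8 after quantile normalization, 8 in the authors' table, 1 with no filter, 0 with the strict filter, 1 with every probe on its own, 26 at 0.10 and 1 with array weights. The 1 group shift became 0 with an estimated correlation, 0 with fry, 2 with no filter, 3 in line 2 alone and 0 in line 14 alone. With replicate number as a block the counts were 1 for both lines, 0 for line 2, 0 for line 14 and 0 for genes called in both; arrays of the same number did not deviate together (r = 0.065, 0.024 and 0.079), so the numbers do not pair the samples. Leaving out each array, with a lone array assumed to vary like the other groups, gave 0 to 106 genes for both lines, 0 to 0 for line 2, 0 to 1 for line 14, 0 to 0 for line 14 against line 2, 0 to 0 for genes called in both and 0 to 3 group shifts. OsMADS29 ranged from -0.45 to -0.16, and from -0.72 to -0.14 with arrays left out, and was never called. Os03g0663900 stayed called in 11 of 11 alternatives other than arrays left out, and in 3 of 6 of those. Os07g0511400 lost its call in 1 of 11, the replicate block (limma adjusted p = 0.145 in a range of 0.00312 to 0.145), and kept it in 2 of 6 with arrays left out. Os01g0822900 lost its call in 7 of 18 and Os03g0195100 in 4 of 11, and each in all 6 with arrays left out. Fewer arrays in a fit leave fewer degrees of freedom; for the other settings the cause was not tested. Signal near background limits most of the calls, since 17 of the 18 genes higher in the lines were not well above it in wild type.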

Other observations

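The lists of microRNA probes matched on signal were chosen after the microRNA probes were seen to lie lower, and the range they would have to fall in was set before they were drawn. For neighbouring loci, the requirement that the intervals be apart was added after the values were seen.

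Of the 98 microRNA probes tested, 62 had a lower and 36 a higher fitted value in the lines, and 0 were called in limma, with 12 at an unadjusted p under 0.05. The smallest adjusted p was that of the 5' flank of osa-miR415, at -1.86 (SE 0.27, limma adjusted p = 0.131), lower on 4 of 4 line arrays. It was well above background on both wild-type arrays and on 1 of 2 arrays in each line, and was chosen after its values were seen.

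Since microRNA probes are dim, 1 possible explanation of their lower median is a shift of dim probes of any kind. Random lists of other probes matched on signal had a median difference of -0.015, with 95% of 10000 lists between -0.26 and 0.23, and the 98 microRNA probes lay outside, at -0.31. The narrower lists lay inside their own ranges, at -0.42 for miR166 (-0.61 to 0.70), -0.35 for mature probes (-0.50 to 0.54) and -0.24 for flanking probes (-0.32 to 0.25). Probes of a family share sequence, so they are not independent and the random lists are too narrow a yardstick.

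If linked chromosome segments differed between the lines and wild type, neighbouring loci could change together more than between arrays of a group. The Spearman correlation between neighbours, in locus order, was 0.033 for the lines minus wild type (95% bootstrap interval 0.020 to 0.047) and 0.041 for the difference of the wild-type arrays (0.028 to 0.054). The intervals overlap, so the test gave no sign of such segments and does not exclude them.

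Different probes of a locus gave related differences, with a Spearman correlation of 0.690 across 6474 loci, and all 6 called loci with another kept probe had the same sign in both.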
